A study of Mus musculus with 18 samples.

How the data were processed

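Gene expression was measured on 18 arrays, 9 of RNA immunoprecipitated with the flag-tagged poly(A)-binding protein (IP) and 9 of whole brain total RNA (WB). Per the labels' protocols, mice of C57BL/6J X DBA/2J background were perfused with formaldehyde, brains were homogenised, the tagged protein was captured on anti-flag beads and the crosslinks were reversed. Per the labels' protocols, 5 ng of RNA was amplified with the NuGEN WT-Ovation Pico system and labelled with biotin. The ages of 11 and 14 weeks are not assigned to samples in the sources used here. The deposited values are intensities made with MAS5, per the submitters' processing notes, which give no version. They are on a linear scale, and the mean of each array without the lowest and highest 2% of values was close to 500. Detection calls were not used here. Groups were taken from the labels.

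For the re-analysis, 16 was added to each deposited intensity and the log2 taken, so that folds understate changes of dim probe sets. No filter on brightness was applied. The 64 array control probe sets were left out and 45037 were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with empirical Bayes variance moderation, an intensity trend and Benjamini-Hochberg adjustment. Counts are given at adjusted p 0.05, and also with a change of at least 2-fold. Of the tested probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none listed. The first kind covered 18193 genes, each represented by the probe set with the highest mean over the 18 arrays. Unless stated otherwise, a gene said to rise or fall did so on that probe set, and its other probe sets often differed. Symbols of 34741 probe sets were matched by Entrez ID to a reference gene table used for names only, and 0 were renamed.

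The genes named follow a rule set before the data were examined. Hcrt, Pabpc1 and Trib2 were always named. Then came the 12 largest rises and 12 largest falls among genes past adjusted p 0.05, changed at least 2-fold, with all 9 arrays of 1 group above all 9 of the other, passing over unnamed clones. From each gene list up to 2 members with the largest rise and 2 with the largest fall were eligible, and any member of the orexin neuron and neuropeptide lists. Exceptions are stated where they occur. The 29 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and again with an estimated correlation. List members were counted with adjustment over all probe sets and over the list alone. RNA quality and array measures were compared by exact permutation over all 48620 divisions of the arrays, with Benjamini-Hochberg adjustment. Control measures chosen later are reported in the closing part, apart from the bacterial transcripts drawn in a figure.

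The limma procedure was tested on simulated data for 45037 probe sets of the IP and WB comparison, 200 of them changed. It recovered 2 of 50 with a log2 change of 0.5, 15 of 50 with 1, 40 of 50 with 2 and 50 of 50 with 4, and called 5 unchanged probe sets. The simulated values were independent, with the same SD in both groups, where the data had a median SD of 0.74 in IP and 0.34 in WB. With 200 changed probe sets against 20257 called in the data, these rates need not hold for this comparison. The alternatives set before the data were examined were pseudocounts of 1 and 64, quantile normalization, median centring, 2 filters on brightness, no intensity trend, array weights, a block for the replicate number, leaving out each array, other probe sets of a gene and the mean over them. Those chosen after the data were seen were scaling on the hybridization controls, leaving out probe sets with shared sequence, leaving out 4 IP arrays together and an Xist covariate. The arrays were also divided at random 100 times, the real division included.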

Results

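Gene expression was measured in brains of transgenic mice that carried a flag-tagged poly(A)-binding protein under the control of the orexin gene's regulatory sequence. Orexin, encoded by Hcrt, is a neuropeptide of the lateral hypothalamus that sustains wakefulness. The poly(A)-binding protein attaches to the tails of messenger RNAs, so that an antibody against the tag can pull down RNA from the cells that express the transgene. The series holds 18 arrays in 2 groups of 9. The first (IP) held RNA recovered by anti-flag immunoprecipitation from formaldehyde-fixed brain, which the labels call polyA RNA, and the other (WB) held total RNA of whole brain. The comparison asks which transcripts were more or less abundant in the immunoprecipitate than in the brain as a whole. Each array gave an intensity for 45101 probe sets, of which 45037 were not array controls. The labels name separate samples but do not say that each came from its own animal, so the p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision of every value.

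Hcrt, the gene whose regulatory sequence drove the transgene, did not pass the test between the groups. Its probe set had a mean of 8.23 ± 0.74 in IP and 8.02 ± 0.42 in WB (log2 intensity, mean ± SD, n = 9 each). The difference of 0.21 (SE 0.28) had an adjusted p of 0.568 in limma, with a 95% confidence interval from -0.37 to 0.80, so that a rise above 1.74-fold lay outside the interval. This bound holds for the deposited scaling only, as the difference ranged from -0.71 to 0.64 over the alternatives. The median intensity was 308 in IP and 247.5 in WB, and 7 of the 9 IP arrays lay above the WB mean. Array IP replicate 2 was far below the others, and without it the difference was 0.43. Pabpc1, the mouse gene of the poly(A)-binding protein, had a difference of -0.14 (SE 0.15, adjusted p = 0.479). The transgene carried a rat cDNA of that protein, and whether this probe set detects it is not given in the sources used here. Trib2, encoding a pseudokinase, is known to have been reported from these samples and so is not independent evidence. The brightest of its 3 probe sets had a difference of 0.35 (SE 0.22, adjusted p = 0.199). Its ID ends in _s_at, a class of shared sequence. The other 2 probe sets changed in opposite directions, by 1.28 (SE 0.38, adjusted p = 0.00775) and by -1.49 (SE 0.39, adjusted p = 0.00263). The former has an ID ending in _x_at, a class that can match several genes. It had a WB mean of 5.56, below the dim trpn control probe sets (IP means up to 6.31), so its size depends on the pseudocount. The latter, which fell, is the only 1 of the 3 outside these classes. The brightest Trib2 probe set passed the threshold under quantile normalization (0.62, adjusted p = 0.0159) and median centring (0.77, adjusted p = 0.00596), and without IP replicate 2 (0.50).

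**Figure D1:**
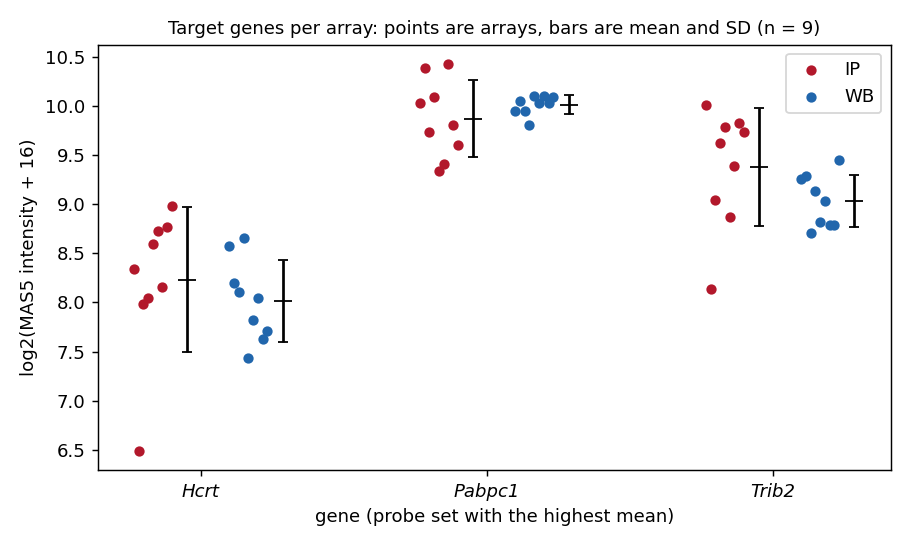
Log2 intensity of Hcrt, Pabpc1 and Trib2 on each array, by group (IP red, WB blue), for the probe set of each gene with the highest mean; black bars give the mean and SD of 9 arrays. The groups overlap for all 3 genes, and the lowest Hcrt value, 6.49, belongs to IP replicate 2.

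Genes described in orexin neurons moved in both directions. Of 11 measured members of this list, 4 rose, 2 fell and 5 did not pass the test. Plagl1, a zinc finger transcription factor, rose 3.52-fold (1.81, SE 0.12, adjusted p = 1.39e-11), and Nptx2, a neuronal pentraxin of synapses, rose 2.4-fold (adjusted p = 5.37e-05). Plagl1 passed on 1 of its 3 probe sets, whose ID ends in _x_at, a class that can match several genes. Vgf, a secretory granule protein, rose 2.35-fold (adjusted p = 6.3e-07) and Dlk1, a Notch-related membrane protein, 1.92-fold (adjusted p = 0.000183). Pdyn, the precursor of dynorphin, fell by 1.30 (SE 0.36, adjusted p = 0.00492), and Igfbp3, an insulin-like growth factor binding protein, fell by 0.90 (adjusted p = 0.00141). Pdyn and Igfbp3 did not pass with quantile normalization, Igfbp3 not with median centring, Dlk1 not with the mean over its probe sets, and Nptx2, Vgf and Dlk1 not with scaling on the hybridization controls. Slc17a6, the vesicular glutamate transporter of hypothalamic neurons, had a difference of -0.09 (adjusted p = 0.772), Lhx9 of -0.06 (adjusted p = 0.841), Scg2 of -0.10 (adjusted p = 0.494) and Ebf2 of -0.54 (adjusted p = 0.190). However, 1 of the 2 probe sets of Slc17a6 passed as lower and 1 of the 4 of Lhx9 as higher. The list had a median of -0.06, a mean of 0.23 and an upward camera direction with an adjusted p of 0.589. Among 14 receptors and channels described in orexin neurons, 3 rose and 3 fell (camera adjusted p = 0.980, upward, with a median of -0.11 and a mean of -0.03). Slc8a1, a sodium-calcium exchanger, rose 3.56-fold, although 2 of its 4 probe sets fell and their mean turned lower (-0.54, adjusted p = 0.00853). Hcrtr2, an orexin receptor, fell by 1.18 (adjusted p = 0.00583) and Npy1r, a neuropeptide Y receptor, by 1.79 (adjusted p = 2.84e-06). The call of Hcrtr2 was lost with quantile normalization and with median centring.

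Other hypothalamic neuropeptides also split. Of 14 measured, 3 rose and 5 fell, and adjusted over the list alone 3 rose and 7 fell (camera adjusted p = 0.600, downward). Only 3 of the 14 had more than 1 probe set. Crh, Ghrh, Npy, Pmch, Trh, Avp and Gal had 1 each, so no other probe set could check their calls. Crh, corticotropin-releasing hormone, rose 4.93-fold from 11.50 ± 0.28 to 13.80 ± 0.51 (log2, mean ± SD, n = 9 each, limma adjusted p = 1.43e-10), and Ghrh, growth hormone-releasing hormone, rose 2.71-fold (adjusted p = 0.00527). Npy rose 1.32-fold (adjusted p = 0.0418), but its difference was -0.52 when arrays were scaled on the hybridization controls, and its call was lost in 9 of 18 fits that left out 1 array. Pmch, the melanin-concentrating hormone precursor made by a neighbouring lateral hypothalamic population, fell 2.23-fold (adjusted p = 4.43e-05). Trh fell 2.36-fold, Pomc 2.26-fold, Avp 1.89-fold and Gal 1.88-fold, with adjusted p-values of 0.00873, 0.0468, 0.0073 and 0.0151. The call of Pomc was lost in 11 of 18 fits that left out 1 array, with values from -1.41 to -0.84 (the latter without WB replicate 8), and with a pseudocount of 64. These 4 calls were lost with quantile normalization and with median centring, and that of Ghrh with scaling on the hybridization controls. Oxt, Sst, Tac1, Hdc, Nts and Cartpt did not pass the threshold, with differences of -0.12, -0.11, 0.08, 0.11, -0.42 and -0.47. Among 16 hypothalamic transcription factors 3 rose and 0 fell, and adjusted over the list alone 1 rose (camera adjusted p = 0.661). With quantile normalization 7 were higher and 0 lower, and with scaling on the hybridization controls 0 and 7. Isl1 rose 2.2-fold (adjusted p = 7.28e-05), but did not pass with the mean over its probe sets or with scaling on the hybridization controls. Of 8 pituitary hormone genes only Pomc fell, and none did so adjusted over the list alone (camera adjusted p = 0.521).

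Of 22 pan-neuronal genes, 10 rose and 10 fell (camera adjusted p = 0.751, downward, with a median of 0.03 and a mean of -0.35). With quantile normalization 6 were higher and 13 lower, and the list passed downward at the preset correlation (camera adjusted p = 0.000193). With median centring 11 were higher and 9 lower (camera adjusted p = 0.506), and with an estimated correlation and the deposited scaling the adjusted p was 0.951. Stx1a, a syntaxin of synaptic release, rose 5.76-fold and Rbfox3, the neuronal nuclear marker, 4.18-fold. Uchl1, a ubiquitin hydrolase, fell 9.86-fold and Tubb3, neuronal tubulin, 9.4-fold. The other probe set of Stx1a and the other 2 of Rbfox3 fell. As the mean over its probe sets Stx1a did not pass (0.10), and Rbfox3 turned lower (-0.72, adjusted p = 0.00241). In the list of forebrain glutamatergic neurons 5 of 14 rose and 6 fell (camera adjusted p = 0.980), with Lmo4 lower by 4.62-fold and Rasgrf2 by 2.81-fold. In the GABAergic list 5 of 13 rose and 4 fell (camera adjusted p = 0.962). Vip, a peptide of cortical interneurons, rose 2.15-fold (not past the threshold with scaling on the hybridization controls), while Pvalb, parvalbumin, fell 4.67-fold and Slc32a1, the vesicular GABA transporter, 4.37-fold. Striatal neuron genes gave 2 rises and 4 falls of 12 (camera adjusted p = 0.589), with Ppp1r1b, the phosphoprotein DARPP-32, down 6.05-fold. Monoamine and cholinergic genes gave 1 rise and 4 falls of 11 (camera adjusted p = 0.589). Th, tyrosine hydroxylase, fell 2.68-fold and Maob, monoamine oxidase B, rose 3.74-fold. Of 13 cerebellar neuron genes 7 rose and 2 fell (camera adjusted p = 0.253). Neurod1, a transcription factor of granule cells, rose 3.72-fold and Cbln3, a cerebellin, 3.68-fold, while Pcp2, a Purkinje cell protein, fell 2.97-fold on its brightest probe set, with all 3 of its probe sets lower.

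In the astrocyte list 5 of 16 rose and 8 fell (camera adjusted p = 0.589). With quantile normalization 3 were higher and 10 lower, and the list passed downward at the preset correlation (camera adjusted p = 0.00196). With median centring 7 were higher and 5 lower (camera adjusted p = 0.529), and with an estimated correlation and the deposited scaling the adjusted p was 0.686. Gfap, the astrocyte intermediate filament, rose 6.52-fold (not past the threshold as the mean over its probe sets) and Gja1, a gap junction connexin, 2.58-fold, whereas Aldh1l1 fell 5.49-fold. In the oligodendrocyte and myelin list 6 of 15 rose and 4 fell (camera adjusted p = 0.589). Sox10, a transcription factor of that lineage, rose 5.46-fold and Mag, a myelin glycoprotein, fell 2.46-fold. Of 8 genes of oligodendrocyte precursors 3 rose and 0 fell (camera adjusted p = 0.495), among them Bcan, the proteoglycan brevican, at 3.46-fold on 1 of 2 probe sets while the other fell. In the microglial list 5 of 16 rose and 5 fell (camera adjusted p = 0.962). Csf1r, a growth factor receptor, rose 3.44-fold, while Aif1, the marker Iba1, and C1qa, of complement, fell to IP means of 5.11 and 6.20. Endothelial and mural genes gave 2 rises and 9 falls of 19 (camera adjusted p = 0.323), with Vtn, vitronectin, down 8.15-fold and Myl9, a myosin light chain, down 7.22-fold. Choroid plexus and ependymal genes gave 2 rises and 1 fall of 14 (camera adjusted p = 0.980, upward, with a median of -0.06). Of 12 genes of meninges and fibroblasts 0 rose and 6 fell, including Apod, apolipoprotein D, by 3.17-fold (camera adjusted p = 0.253). Of 6 red blood cell genes 0 rose and 3 fell (camera adjusted p = 0.253). Hba-a2, an alpha globin, fell 24.4-fold and Hbb-b2, a beta globin, 12.6-fold. Hba-a1, named here after its value was seen, had a difference of -0.48 (adjusted p = 0.265), and since the globin copies are nearly identical these probe sets may not tell them apart.

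Cytosolic ribosomal protein genes were lower in IP, with 4 of 29 higher and 17 lower, or 4 and 18 adjusted over the list alone. The list's median was -0.68, and it was the only one of the 29 lists past the threshold with the deposited scaling and the brightest probe set of each gene (camera adjusted p = 0.000132). With an estimated correlation its adjusted p was 0.278, and 0 lists passed. Rplp2 fell 9.19-fold and Rps14 fell 8.67-fold on its brightest probe set, with both of its probe sets lower, while Rpl13a rose 2.36-fold and Rps9 rose 2.29-fold, each with another probe set that fell. As the mean over probe sets both turned lower, Rps9 at -1.09 (adjusted p = 0.000125) and Rpl13a at -0.25 (adjusted p = 0.119). Rpl13a did not pass with quantile normalization, and the list was lower under every scaling tried. Genes of oxidative phosphorylation gave 17 rises and 23 falls of 47 (camera adjusted p = 0.495). With quantile normalization 7 were higher and 34 lower and the list passed downward (camera adjusted p = 1.36e-13), as it did with the mean over each gene's probe sets (camera adjusted p = 0.000185). These p-values used the preset correlation, and with the deposited scaling and brightest probe sets the adjusted p was 0.705 with an estimated correlation. With median centring 20 were higher and 13 lower (camera adjusted p = 0.403). Atp5b, the beta subunit of ATP synthase, fell 18.2-fold and Atp5e, its epsilon subunit, 10.6-fold. Cox5a, of cytochrome oxidase, rose 3.14-fold and Ndufv2, of complex I, 2.96-fold, each on 2 of 3 probe sets while 1 fell. Genes of poly(A) binding and translation initiation gave 9 rises and 5 falls of 19, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.589, upward). With quantile normalization the direction turned, with 4 higher and 9 lower (camera adjusted p = 0.0156, downward, at the preset correlation). With median centring 10 were higher and 3 lower (camera adjusted p = 0.506, upward), and with an estimated correlation and the deposited scaling the adjusted p was 0.686. Paip2, an inhibitor of the poly(A)-binding protein, rose 2.41-fold (not past the threshold with scaling on the hybridization controls) and Eif3b fell 3.91-fold. Replication-dependent histones, a class whose messages mostly lack a poly(A) tail, gave 2 rises and 1 fall of 6 (camera adjusted p = 0.589). Whether the messages measured here had a tail was not tested. H2bc21 rose 5.52-fold on 1 of 2 probe sets while the other fell, and H1f4 fell 4.76-fold. Of 13 long noncoding RNAs 6 rose and 3 fell (camera adjusted p = 0.589). Meg3, a maternally expressed noncoding RNA, rose 5.24-fold on its brightest probe set, while 7 of its 11 probe sets fell and their mean turned lower (-0.84, adjusted p = 4.98e-07).

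Of 17 immediate early genes 7 rose and 0 fell (camera adjusted p = 0.253), led by Fos at 3.01-fold and Egr2 at 2.98-fold, both activity-induced transcription factors. When arrays were scaled on the hybridization controls instead, 1 of these genes was higher and 6 were lower, and neither Fos nor Egr2 passed. Of 14 heat shock and stress genes 6 rose and 3 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.399). With quantile normalization 4 were higher and 4 lower, and with scaling on the hybridization controls 3 and 8. Hspa1b and Hspa1a, inducible chaperones with nearly identical sequences, rose 6.15-fold and 5.23-fold, and Hspb1, a small heat shock protein, fell 3.35-fold on 1 of 2 probe sets, with a mean over both that did not pass. Of 18 circadian clock genes 4 rose and 6 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.521). Per1, a clock repressor, fell to an IP mean of 5.21, and Rora, a nuclear receptor, fell 4.42-fold, with all 9 of its probe sets lower. Of 39 olfactory receptor genes 5 rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.755). With quantile normalization 10 were higher and 0 lower, with median centring 13 and 0, and with scaling on the hybridization controls 0 and 23. Keratin, sperm and other genes of tissues outside the brain gave 3 rises and 4 falls of 18, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.962, upward, with a median of -0.02 and a mean of 0.03). These counts were 8 higher and 0 lower with quantile normalization and with median centring, and 0 and 10 with scaling on the hybridization controls. Under that last scaling more members were lower than higher in each of the 29 lists. In 20 of the 29 lists the counts adjusted over the list alone equalled those over all probe sets. With quantile normalization the camera direction also turned downward, without passing, for the lists of receptors and channels, cerebellar neurons, oligodendrocytes, long noncoding RNAs and heat shock. The 29 lists were tested together, and those listed without a direction had a median, mean and test of the same sign.

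**Figure D2:**
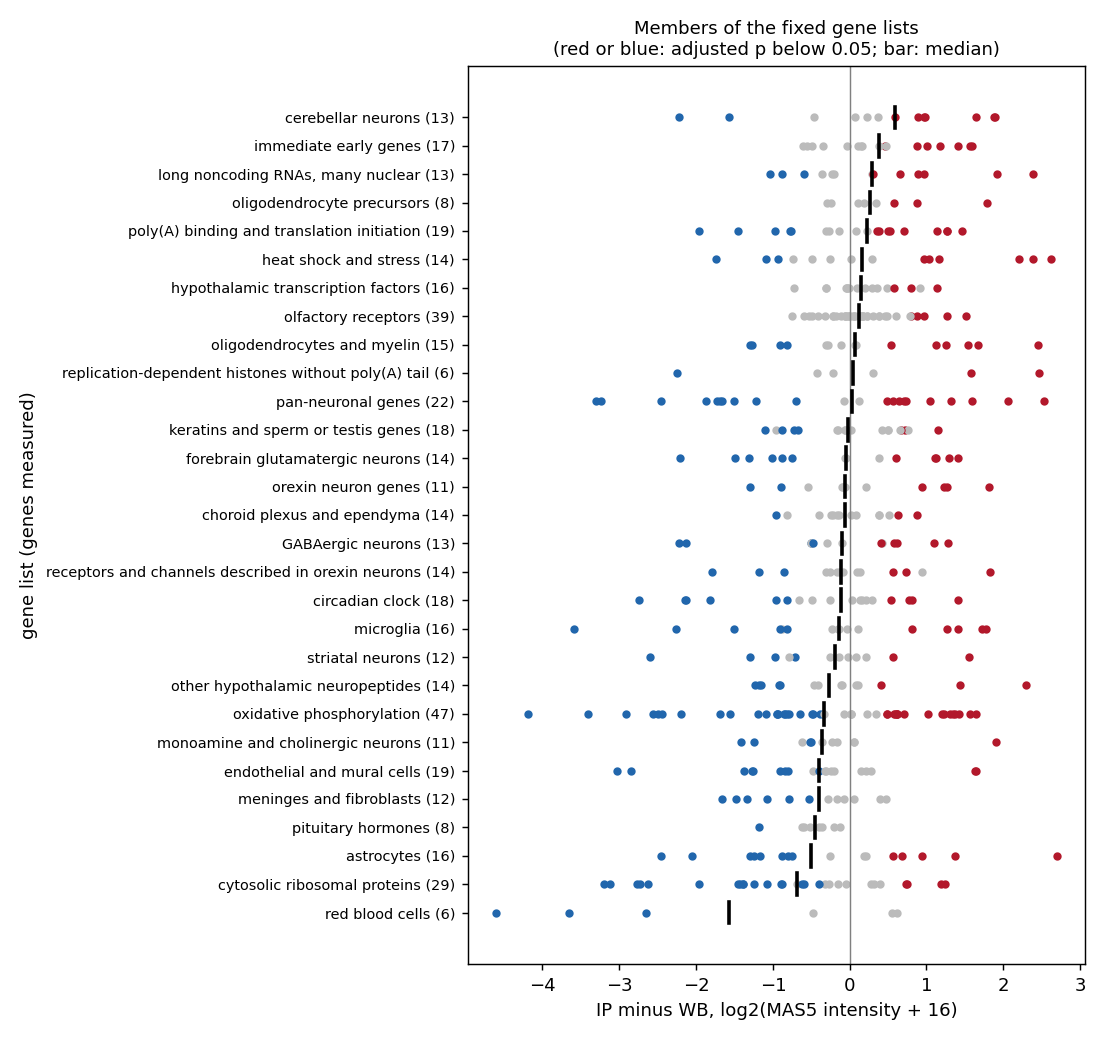
IP minus WB difference (horizontal axis, log2 of intensity plus 16) of each measured member of the 29 gene lists (vertical axis, with the number measured), ordered by median. Red and blue points passed adjusted p 0.05, grey points did not, and black bars mark medians, from -1.57 for red blood cells to 0.59 for cerebellar neurons.

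Across all probe sets, 6403 were higher and 13854 were lower in IP at adjusted p 0.05 (limma with Benjamini-Hochberg adjustment), and 3475 and 9862 of these changed at least 2-fold. Higher probe sets made up 31.6% of the calls with the deposited scaling, 52.3% with quantile normalization, 60.6% with median centring and 4.21% with scaling on the hybridization controls. The median difference over all probe sets was -0.23 as deposited, 0.11, 0.20 and -1.15 under those alternatives, so changes of this size depend on the scaling. Over 1 probe set per gene, 3944 of 18193 genes were higher and 3947 lower. That probe set was the brightest of each gene, and of the 4504 brightest probe sets 52% were higher and 25.5% lower. The counts over genes and gene lists therefore depend on this choice of probe set. All 9 arrays of 1 group lay above all 9 of the other for 2900 genes, against 0.00411% of genes by chance.

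With a pseudocount of 16, the 12 largest rises that met the fixed rule ranged from 10.2-fold to 13.6-fold. Man2c1, a mannosidase, rose 13.6-fold from 8.53 ± 0.53 to 12.29 ± 0.25 (log2, mean ± SD, n = 9 each, limma adjusted p = 1.14e-13). Next came Fastkd2 (13.3-fold), a mitochondrial RNA-binding protein, Ctu2 (13.1-fold), a tRNA-modifying enzyme, Ccm2 (12.8-fold), a scaffold protein of vessels, and Ajap1 (12.8-fold), an adherens junction protein. Adamts20, a metalloprotease, rose 12.6-fold and Polr2a, the largest subunit of RNA polymerase II, 11.8-fold. Hacd1, Mup10, Chfr, Sbk1 and Thbs2 rose 11.6-fold, 10.4-fold, 10.4-fold, 10.3-fold and 10.2-fold. The probe sets of Ctu2, Ajap1, Chfr and Thbs2 have IDs ending in _x_at, a class that can match several genes. Of all probe sets in that class 41% were higher in IP, so these rises may not belong to the named genes alone. That of Hacd1 ends in _s_at, also a class of shared sequence. Of the 10 with more than 1 probe set, 3 (Man2c1, Fastkd2 and Sbk1) had another probe set that fell, and 0 had all probe sets higher. The order depends on the pseudocount, as for the dim Mup10 (WB mean 4.92), which came first among these 12 with a pseudocount of 1 and last with 64. The 12 largest falls ranged from 12.6-fold to 24.4-fold. Besides the globins Hba-a2 and Hbb-b2 and Atp5b, they included Bex2 (22.8-fold), a brain-expressed X-linked protein, Ncs1 (18.9-fold), a neuronal calcium sensor, and Mlc1 (16-fold), an astrocyte membrane protein. Gde1, Srsf5, Dctn3, Usp12, Cops6 and Ckmt1 fell 15.6-fold, 15.5-fold, 15.3-fold, 14.7-fold, 13.5-fold and 13.5-fold. Of the 5 with more than 1 probe set, Ncs1, Usp12, Ckmt1 and Hbb-b2 had all probe sets lower, and Cops6 had 1 higher. The adjusted p was at most 6.48e-08 for the 24 genes together. IP means of Hba-a2, Ncs1, Aif1, Per1, C1qa, Aldh1l1, Myl9, Eif3b and Pdyn also lay below 6.31, the highest mean of the dim trpn control probe sets, as did WB means of Mup10, Thbs2 and Ghrh, so that the folds of these genes depend on the pseudocount.

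Probe sets of the same gene often disagreed. Of 3826 genes with at least 2 probe sets past the threshold, 1985 (51.9%) had calls in both directions, against 53.2% if directions were drawn at random with the overall share. That share was close to the random one. With the deposited scaling, the direction of 1 called probe set therefore told little about that of another of the same gene. The rises and falls given above for single probe sets may not hold for the gene as a whole. The next 4 genes were chosen as examples after their values were seen. For Mbp, myelin basic protein, 4 probe sets rose, by up to 1.12 (SE 0.19), and 4 fell, the lowest at -3.19 (SE 0.30). For Camk2a, a kinase of excitatory synapses, 1 probe set rose by 1.40 (SE 0.09) and 5 fell, the lowest at -3.34 (SE 0.27). For Ttr, transthyretin of the choroid plexus, values ranged from -3.49 to 0.89, and for Malat1, a nuclear noncoding RNA, from -1.68 to 1.35. Genes with at least 3 probe sets that all passed in 1 direction numbered 13 higher and 217 lower, and 4 and 206 without probe sets of shared sequence. Only 31.6% of all calls were higher, so an excess of genes lower on all probe sets follows in part from that share. With quantile normalization the genes higher and lower on all probe sets numbered 55 and 136. Then 49.6% of genes with at least 2 called probe sets had calls in both directions, against 60% expected at random.

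Measures of RNA quality moved with the groups. The 3' over 5' log2 ratio of Gapdh was 4.13 ± 0.66 in IP and 1.56 ± 0.15 in WB (mean ± SD, n = 9 each, exact two-sided permutation adjusted p = 6.58e-05, where 4.11e-05 is the smallest unadjusted p the 48620 divisions allow). That of Actb was -0.35 ± 0.44 in IP and -0.17 ± 0.08 in WB (exact permutation adjusted p = 0.273), while all 3 of its segments were lower in IP, the 3' segment at a mean log2 value of 9.90 against 12.56. The 5' segment of 18S rRNA had a difference of -3.51 (log2, permutation adjusted p = 6.58e-05). Its 3' segment differed by -0.90 (permutation adjusted p = 0.000439) and its middle segment had means of 14.85 in IP and 15.06 in WB (permutation adjusted p = 0.273, but -1.15 with an adjusted p of 4.94e-05 after quantile normalization). Control segments of pyruvate carboxylase and the transferrin receptor, not tested, lacked a larger loss at the 5' end. Their 5' segments differed by 0.32 and -1.20 and their 3' segments by -2.09 and -1.15. The pyruvate carboxylase 3' segment was dim in IP (mean 5.93). IP arrays had a lower median log2 value (7.61 ± 0.12 against 8.04 ± 0.10) and a wider interquartile range (2.77 ± 0.06 against 2.46 ± 0.10), each with an exact permutation adjusted p of 6.58e-05 (n = 9 each). They correlated less with the other arrays of their group, at a mean of 0.846 against 0.940 (permutation adjusted p = 6.58e-05). The median SD over probe sets was 0.74 in IP and 0.34 in WB.

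**Figure D3:**
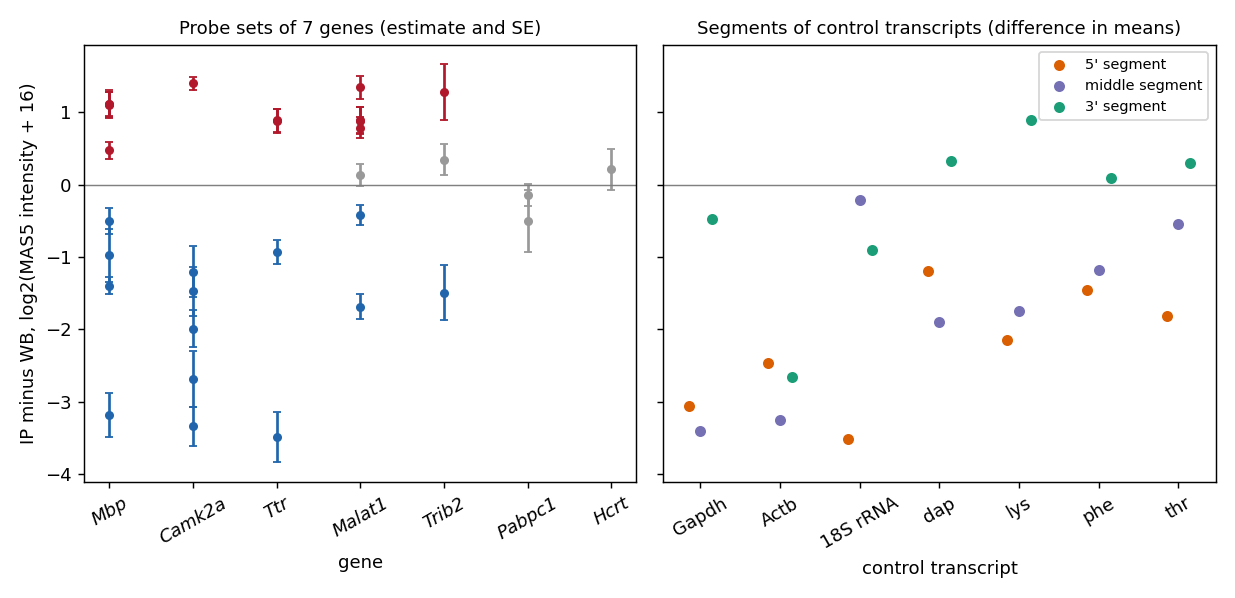
Left, IP minus WB difference (vertical axis, log2 of intensity plus 16) with its SE for each probe set of 7 genes, red or blue where adjusted p was below 0.05. Right, the difference in group means for the 5', middle and 3' segments of 3 mouse control transcripts and 4 bacterial ones (dap, lys, phe and thr, chosen after the data were seen), whose 5' segments were all lower in IP.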

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

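The division of the arrays at random was planned, as were quantile normalization and most of the alternatives counted for Hcrt, but their use to weigh explanations, and the tests on control probe sets, shared sequence, brightness classes and non-neuronal markers, were chosen after the results were seen. Of 100 divisions of the 18 arrays into 9 and 9, 1, the real one, gave as many probe sets past the threshold (20257). The highest other gave 12532, with 8 of the 9 IP arrays on 1 side. A share of 1 in 100 is the smallest this draw allows, so chance is argued against but not excluded.

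Probe sets of the same gene often passed the threshold in opposite directions. Breakage of brain RNA alone, before the bacterial control transcripts were added, is argued against by those transcripts, whose 3' over 5' log2 ratio was 2.06 higher in IP (exact permutation p = 4.11e-05, the smallest possible). Shared sequence as the whole cause is argued against because 47.1% of genes were still called both ways without such probe sets, where 45.5% are expected if directions are drawn at random (51.9% and 53.2% with them). Loss of parts of transcripts in amplification or labelling is a candidate explanation, since the 5' probe sets of the bacterial controls differed by -1.66 (exact permutation p = 0.000247) and the 3' ones by 0.40 (p = 0.255). The step at which these transcripts were added is not given in the sources used here, and no biological explanation was tested.

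Probe sets whose ID ends in _x_at, which can match several genes, were higher in IP for 41% against 12.7% of the others. Unequal distributions of the arrays are argued against, as the ratio of these shares was 3.23 as deposited and 2.14 after quantile normalization. Brightness alone is argued against by an odds ratio of 3.45 (95% interval 3.12 to 3.81) within classes of similar brightness. After quantile normalization it was 2.73 (2.51 to 2.97). These intervals treat probe sets as independent, although those of shared sequence need not be. Brightness also still varies within a class. Cross-hybridization stays open, and no biological explanation was tested.

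Hcrt and the list of orexin neuron genes were not higher in IP by their tests. Whether the processing setting hides a rise of Hcrt cannot be told. Hcrt passed and was higher in 0 of 9 alternatives of pseudocount, scaling, filter or variance model. In 3 of them its difference moved by more than its SE, up to 0.64 with median centring (adjusted p = 0.0617). The lowest over all its alternatives was -0.71. Median centring shifts all probe sets of an array alike, so that move is not particular to Hcrt. RNA of other brain cells in the immunoprecipitate stays a candidate explanation that was not decided. Of non-neuronal markers 2% (1 of 50) fell by at least 3 log2 units, but so did only 0.72% of all genes that bright. A low share was therefore likely for any genes, and that share alone cannot tell whether such RNA was present. Of the 50 markers 19 were called higher and 18 lower, with a median difference of 0.07. An IP mean log2 of at least 9 was kept by 41 of them, where the dim trpn control probe sets had IP means up to 6.31. Signal of non-neuronal markers was thus present in IP. Whether it hid a rise of Hcrt was not tested. Abundant glial transcripts went both ways, with IP and WB means of 14.90 and 13.53 for Gja1 and 15.38 and 14.26 for Mbp on _x_at probe sets, but 10.12 and 13.31 for another Mbp probe set and 10.38 and 12.43 for Aldoc. Hcrt has 1 probe set, so a loss at its position stays open, and no biological explanation was tested.

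Outliers by Dixon's test were sought in 286 groups of 9 arrays, where 14.3 are expected by chance, and 22 were found, 8 in IP and 14 in WB. In IP, the arrays far from the others were replicate 2 for Hcrt (6.49), replicate 7 for Ccm2 (12.63), Ajap1 (12.01) and Pdyn (8.46), replicate 6 for Vip (8.95) and Odf1 (9.41), replicate 9 for Apod (10.04) and replicate 3 for Rplp2 (7.42). In WB they were replicate 9 for Fastkd2 (9.72), Nptx2 (8.19), Sst (9.46), H1f2 (11.17) and Zpbp (5.04), and replicate 8 for Hbb-b2 (13.76), Pdyn (6.03), Pomc (11.71) and Olfr17 (6.68). The others were WB replicate 4 for Bex2 (10.75), Rbfox3 (11.01) and Th (6.89), and WB replicate 5 for Maob (7.25) and for the Actb 3' over 5' log2 ratio (0.03).

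Control probe sets outside the comparison also differed between the groups. The hybridization controls were 0.92 higher in IP (log2, exact permutation p = 4.11e-05), and 1 B2 repeat probe set was 0.75 higher (exact permutation p = 0.000206). Another B2 repeat probe set was 0.30 higher, without a test, and the B1 repeat probe set 0.10 higher (exact permutation p = 0.623).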

How the results depend on the processing

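Scaling on the hybridization controls, the 5 IP arrays, the Xist covariate and leaving out shared-sequence probe sets were chosen after the data were seen; the cause of the changes below was not tested. Probe sets higher and lower numbered 10869 and 9908 with quantile normalization (at least 2-fold 5686 and 6654), 12802 and 8322 with median centring (7320 and 5774) and 1326 and 30144 with hybridization control scaling (607 and 25392). Among probe sets brighter than the median 5027 were higher and 8479 lower (2513 and 5313 at least 2-fold), and in the brightest 11259 probe sets 3949 and 3914 (2063 and 2178), with fewer tested. Leaving out 1 array gave 5921 to 6507 higher and 13057 to 14031 lower. Trib2 passed with quantile normalization (0.62), median centring (0.77), the 5 IP arrays with the lowest hybridization controls (0.53), and its other probe sets (-1.49 and 1.28), and ranged from 0.27 to 0.50 with 1 array left out, passing without IP replicate 2. Pabpc1 passed with hybridization control scaling (-1.06). Hcrt ranged from -0.71 to 0.64 over 31 alternatives, 18 of which left out 1 array, with adjusted p from 0.0617 to 0.762, and had no value among the brightest 11259. With quantile normalization Kcnj3 (-0.13) and Ttr (-0.25) reversed, the middle 18S rRNA segment passed (-1.15), and camera adjusted p was 0.000193 for pan-neuronal genes, 0.00196 for astrocytes, 1.36e-13 for oxidative phosphorylation and 0.0156 for poly(A) binding and translation initiation, whose direction turned downward. Oxidative phosphorylation also passed with the mean over probe sets (0.000185), and ribosomal proteins did not with an estimated correlation (0.278). With the mean over a gene's probe sets these reversed: Slc8a1 (-0.54), Kcnj3 (-0.76), Rbfox3 (-0.72), Camk2a (-1.55), Bcl11b (-0.45), Gad1 (-1.02), Pde10a (-0.73), Cnp (-0.67), Ptprz1 (-0.10), Ttr (-0.66), Rpl13a (-0.25), Rps9 (-1.09), H1f2 (-0.04), Meg3 (-0.84) and Dbp (-0.34). With hybridization control scaling these did: Kcnj3 (-0.18), Npy (-0.52), Six6 (-0.12), Pde1b (-0.35), Ptprz1 (-0.042), Ttr (-0.037), Ccdc153 (-0.29), Npas2 (-0.11) and Ins2 (-0.20). The replicate block gave 6313 higher and 13707 lower, and 19486 of the 20257 calls held in the same direction. Among the genes eligible to be named it ended the calls of Npy, Ins2 and Krt5 and no other. Same-numbered arrays had deviations correlated from -0.05 to 0.08, 0 of 9 over 0.1. Only 2 IP arrays correlated best with their own number, so the numbers were not used as pairs. Signal over background limits dim probe sets.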

Other observations

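The genes below were chosen after the data were seen, by the rule that at least 3 probe sets all passed in 1 direction. Without probe sets of shared sequence the rule was met by 4 genes higher in IP, against 13 with them. The genes named here were taken with all probe sets counted, so those named as higher need not be these 4. Dnmt1, the maintenance DNA methyltransferase, was higher in IP by a mean of 2.37 over 3 probe sets (SE 0.13, adjusted p = 1.25e-11). Since the rule picked genes by calls on these same arrays, this p-value adds no support. Thoc1, of the mRNA export complex, was higher by 1.68 over 5 probe sets, Hnrnpa2b1, an RNA-binding protein, by 1.58 over 4, and Morf4l2 by 1.57 over 4. Among genes lower on all probe sets, Ncs1 had a mean of -2.69 over 3, Atp6v1b2 and Atp6v0a1, of the vacuolar proton pump, of -2.68 and -2.53 over 4 each, Pfkp, a phosphofructokinase, of -2.55 over 3, Mgll, monoglyceride lipase, of -2.46 over 4 and Mapt, the protein tau, of -2.38 over 4.

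Xist, transcribed from the inactive X chromosome of females, had signal in 2 IP and 4 WB arrays. Its lowest log2 value with signal was 12.02 and its highest without was 9.18. Of 9 pairs of arrays with the same replicate number, 4 differed in this signal.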
